A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

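Budding yeast cells (Saccharomyces cerevisiae) of strain MDY513, which lacks HTZ1, the gene for the histone variant H2A.Z, were arrested in G1 with 4 µg/mL of the mating pheromone alpha factor for 4 hours and moved into galactose medium (2%), per the labels. The cells carried 2 tagged versions of histone H3. H3-Myc was made constitutively and H3-Flag was induced by galactose, so that Flag over Myc at a locus compares recently made H3 with H3 of all ages. After 180 min, chromatin was immunoprecipitated with anti-Myc and with anti-Flag antibody, amplified by linear amplification through RNA, and hybridised to 2-colour 44K tiling arrays. The Myc precipitate was in Cy5 (red) and the Flag precipitate in Cy3 (green) on both arrays, per the labels. The samples form 1 group of 2 replicates, with no other strain, time point or dye swap among the samples analysed here, so no group was compared with another. The labels do not say whether the replicates came from separate cultures. The limma p-values described below therefore measure the spread between these 2 arrays, which may be technical. The p-values of the rotation test, of permuted genes and of camera at its preset correlation compare probes or genes, which are not replicates.

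The spot intensity values were made with Agilent Feature Extraction 8.5.1.1, per the file headers, with spatial detrending on and surrogate values for signals that were not above background. The median ratio of the deposited processed intensity to the background-subtracted signal was 7.75 for Flag and 3.58 for Myc on replicate 1. On replicate 2 it was 12.7 and 4.72. Whether that ratio is the same for every spot of a channel was not checked. The deposited log10 ratio is red over green, Myc over Flag, per the file headers. The deposited value table holds the log2 of the same red over green processed signals, uncentred, to within 4.9e-08, with medians of 0.37 and 0.35, and its sign was turned here. The build of the probe coordinates is not given in the sources used here, and all coordinates are those of the files.

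Each array's log2 Flag over Myc was taken from the processed signals and centred on the median of its used probes (-0.46 before centring on both arrays). A value of 0 is therefore the array's own median and not an equal amount of both histones. Of 41282 nuclear probes, 3964 that were not well above background in both channels on both arrays and 2419 with an outlier flag were left out, which kept 34899. No probe was saturated. Each probe is 60 bp long and neighbouring probes start 267 bp apart (median). The 136 mitochondrial probes were kept apart.

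The files list the features near each probe and call each probe promoter or inside. That word was not used, because the listed distances run from the left end of a gene on either strand. The files called 98.1% of the probes in reverse-strand reading frames promoter, against 99.9% of forward-strand ones inside. Left ends were derived from the listed distances and were consistent for all 6593 reading frames. Frame lengths came from a reference gene table of assembly R64, which matched 5927 frames. Another 19 were left out because the listing contradicted the length, and 5908 were used. No coordinate of that assembly is printed, since only 17.5% of frames had the same left position in it. A frame length is the span from start to stop codon and includes any intron between them. Probes in such introns therefore count as coding. The 666 unmatched frames, the files' names for them and a dubious class were not used. Probes were coding (midpoint in a frame), promoter (within 500 bp upstream of a start codon and in no frame), 3′ intergenic (between 2 convergent genes) or other. A gene's value is the mean of its used probes in the region. Probes between divergent genes count for both genes, which then share a value and enter counts and list tests separately.

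Tests used limma 3.58.1 in R 4.3.3, with lmFit on an intercept, eBayes and Benjamini-Hochberg adjustment at 0.05, for probes, promoters and coding regions. They ask whether a region lies off the array median. For promoters limma estimated 1 common spread for all regions, which makes those p-values very small. Differences between classes of probes were tested two-sided by rotating the ratios along the genome 10000 times, a permutation test whose smallest p is 0.0001. The arrays alone cannot give an exact two-sided sign-flip p below 0.5. Before the data were examined, 22 gene lists were fixed: galactose regulon, pheromone response, histones, cytosolic and mitochondrial ribosomal proteins, proteasome, ribosome biogenesis, glycolysis, glucose-repressed genes, respiration, stress response, phosphate regulon, meiosis and sporulation, silent mating loci, COS genes, PAU, DAN and TIR genes, 3 cell cycle lists, histone chaperones and remodellers, amino acid biosynthesis, and strain markers. Lists with at least 3 measured genes were tested with camera at its preset inter-gene correlation of 0.01. The named genes were fixed by rule in the same way: the 10 highest and 10 lowest named promoters and coding regions past the threshold with the same sign on both arrays, the 2 highest and 2 lowest of each list, and HTZ1, GAL1, GAL10, GAL7 and GAL2. Any other gene was chosen after its value was seen. The comparisons of the middle with the last part of frames and of 3′ intergenic with coding probes were added after the data were examined. Location tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

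The limma test of probes and the rotation test were tried on simulated data with the real spread. For limma the noise was independent, with variances drawn from its own fitted model, so its error rates below hold under that model only. The limma tests of promoters and of coding regions were not tried. Of 200 probes shifted by 1 or 2 log2 units among 34899, all were recovered, with 13 false calls, or 6.10% of the calls. With all but 17473 of the probes shifted, 76.2% of the shifted ones were called and 2.53% of the calls were false. With no shift, the rotation test fell below 0.05 in 8 of 100 simulations for promoters against coding regions and in 3 of 100 for chromosome ends. Camera was tried on 100 lists of 30 genes drawn at random from the real coding values, and 4 fell below 0.05. Genes drawn at random do not share regulation as the fixed lists may, so this does not give the false call rate of those lists. Promoter lists were not tried. Alternatives were normexp background correction (offset 50), loess, scaling between arrays, the value table, no dim filter, each replicate left out, promoters of 250 bp, paired differences per gene, other distances from chromosome ends, an estimated correlation, fry, an intensity trend and a threshold of 0.1. The median spot was 5.65 and 3.69 times its local background in the Flag channel and 9.78 and 8.42 times in the Myc channel of replicates 1 and 2. The number of arrays, 2, limits the precision of each value.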

Results

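The ratio of galactose-induced H3-Flag to constitutive H3-Myc was measured across the genome of yeast cells without H2A.Z, held in G1 by alpha factor, 180 min after the move to galactose. A high ratio marks DNA where recently made H3 made up more of the H3 than at the median probe. A group of 2 replicate arrays was analysed. The arrays correlated at Pearson r = 0.97 and Spearman rho = 0.96 across 34899 nuclear probes, which describes probes and not independent replicates. The SD across probes was 1.32 log2 units, against a median SD of 0.16 between the arrays for the same probe. Values below are log2 Flag over Myc relative to the array median, as the mean ± SD of the 2 arrays.

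The deleted gene was checked first. The single probe in the HTZ1 reading frame (chromosome 15, 303821 to 303880) was not well above background in either channel on either array. Over all nuclear probes, 2.42% were that dim in both channels on both arrays, and 0.17% of coding probes were. Upstream of the frame, DNA was detected, and the HTZ1 promoter probe stood at 1.75 ± 0.03 (n = 2; limma adjusted p = 7.2e-25). The frame of BAR1, which codes for the secreted protease that degrades alpha factor, was also nearly dark: of its 6 probes, 1 was well above background on replicate 1 and 0 on replicate 2. All probes in the frames of the other strain markers were well above background on both arrays, among them HHT1 and HHT2 (histone H3), URA3, LEU2, TRP1, HIS3, LYS2, ADE2, MET15 and CAN1. HHF1 and HHF2 have no coding probe here. The labels do not give the ends of the HTZ1 deletion.

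How far incorporation of new H3 varied along the genome was asked first at single probes. Of 34899 probes, 14131 lay above the array median and 13983 below it at a limma adjusted p under 0.05, and 6785 did not pass. A distance of more than 1 log2 unit was reached by 8844 probes on the high side and 7099 on the low side. The distribution had a long upper tail, with a 99th percentile of 3.67 and a 1st percentile of -1.98. Because each array is centred on its median, similar numbers on either side are built into the test.

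Promoters were mostly above the array median. Of 4543 genes with a promoter probe, 3448 were higher, 314 were lower and 781 did not pass, and the median promoter stood at 0.99. The highest were PUT4, the proline permease, at 4.54 ± 0.01 (23.3-fold over the median) and AGP1, a broad amino acid permease, at 4.37 ± 0.11. Next came the DNA shared by PUS2, a pseudouridine synthase, and MRH4, a mitochondrial helicase, at 4.33 ± 0.11, and the DNA shared by the histone genes HHF2 and HHT2 at 4.30 ± 0.01. ACA1 and STP4, which code for transcription factors, stood at 4.26 ± 0.30 and 4.25 ± 0.32. PET494, a mitochondrial translational activator, was at 4.22 ± 0.15, and RMI1, a partner of the Sgs1 helicase, at 4.21 ± 0.12. At the other end, PAU8, a seripauperin gene next to the left end of chromosome 1, had -2.11 ± 0.09 (4.33-fold below the median). The pheromone-regulated membrane protein gene PRM7 had -1.98 ± 0.08 and PAU20 had -1.73 ± 0.18. EMA35 followed at -1.65 ± 0.19, and the DNA shared by HMRA1 and HMRA2 in the silent HMR cassette at -1.55 ± 0.22. DCG1 (-1.50 ± 0.22), VBA3 (-1.47 ± 0.17), CFF1 (-1.45 ± 0.01) and ADY3 (-1.44 ± 0.11), which acts in spore formation, completed the 10 lowest. The limma adjusted p of these 20 promoters was at most 2.3e-17. Most of the 20 rest on 1 probe, and PAU genes have near-identical copies that a probe can also read. The probes between HMRA1 and HMRA2 can likewise read the same DNA at MAT in cells that answer alpha factor.

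Coding regions split almost evenly. Of 5588 genes, 2185 had a higher ratio than the array median, 2394 a lower one, and 1009 did not pass. Coding probes were 25879 of the 34899 that set the array median, so much of this even split is built in by the centring. The highest were CCW12, a cell wall mannoprotein, at 4.76 ± 0.18 (27.1-fold over the median) and AHP1, a thiol peroxidase, at 4.58 ± 0.01. YCH1, a phosphatase, stood at 4.55 ± 0.30, and SED1, a cell wall protein, at 4.37 ± 0.21. LSM5, a subunit of the Lsm ring in mRNA decay, was at 4.35 ± 0.16. GAL2, the galactose permease, was among these 10 at 4.34 ± 0.08. The remaining ones were BUR6 (4.32 ± 0.14), a transcription regulator, JIP3 (4.31 ± 0.23), RMI1 (4.29 ± 0.38) and CUE4 (4.25 ± 0.29). The lowest were CIN10 at -1.97 ± 0.12 (3.92-fold below the median), VTH2, a sorting receptor homolog, at -1.93 ± 0.09 and ENA2, a sodium pump, at -1.91 ± 0.00. PHO12, an acid phosphatase, had -1.87 ± 0.58 and HMLALPHA1, in the silent HML cassette, -1.74 ± 0.16. EMA35 (-1.72 ± 0.06), FRT2 (-1.68 ± 0.07), SKN7 (-1.66 ± 0.09), a response regulator, YPS5 (-1.66 ± 0.10) and MKT1 (-1.62 ± 0.00) followed. The largest limma adjusted p among these 20 was 4.4e-05, for PHO12. CCW12, YCH1, LSM5, JIP3, CUE4, PHO12, HMLALPHA1 and YPS5 rest on 1 probe each. VTH2, ENA2 and PHO12 have close paralogs whose DNA a probe can also read.

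The genes of galactose use had among the highest ratios in the genome across their frames. The GAL1 frame (galactokinase) stood at 4.20 ± 0.07, or 18.4-fold over the median, GAL10 (epimerase and mutarotase) at 4.03 ± 0.08 and GAL7 (uridyltransferase) at 3.80 ± 0.05. The DNA between GAL1 and GAL10, which holds their shared promoter, was lower than either frame at 2.33 ± 0.19, and the GAL7 promoter stood at 2.25 ± 0.03. The limma adjusted p was 1.8e-07 for each of the 3 frames and at most 9.0e-40 for the promoters. The high ratio ended within the neighbours. FUR4, the uracil permease downstream of GAL1, had -0.36 ± 0.33 in its frame (adjusted p = 0.029), a call that loess and scaling ended. It stood at -0.60 without replicate 1 and -0.13 without replicate 2. The 2 promoter probes of GAL1 and GAL10 can also read any construct of the strain that holds the same DNA.

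**Figure D1:**
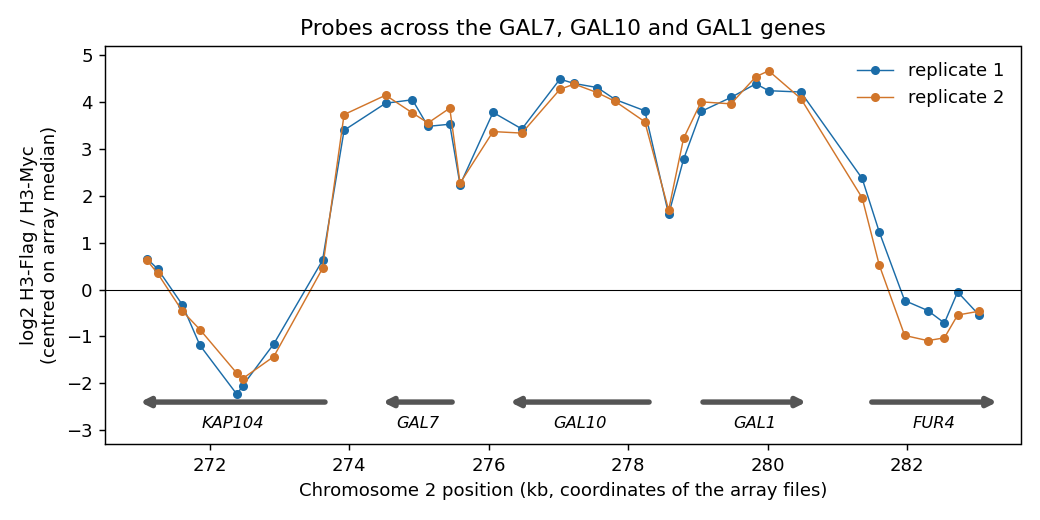
Each point is 1 probe on chromosome 2 from 270948 to 283345, with the log2 ratio of H3-Flag to H3-Myc of each replicate (2 colours) on the vertical axis and arrows for reading frames in their direction of transcription. Both replicates sit near 4 over the GAL7, GAL10 and GAL1 frames, dip at the 2 promoters between them and fall to the array median or below inside KAP104 and FUR4.

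Promoters had a higher ratio than coding regions. The mean was 1.15 ± 0.06 over 5569 promoter probes and -0.12 ± 0.02 over 25879 coding probes, a difference of 1.27 ± 0.09 (n = 2), or 2.41-fold (permutation p = 0.0001 by rotation along the genome, the smallest it can give). Paired within 4396 genes, the promoter was above the coding region on both arrays in 77.3% of genes and below it on both in 14.7%, and the mean difference was 0.89 ± 0.10. Part of this was shared by other DNA outside frames. Probes between convergent genes, at 3′ ends only, averaged 0.48 ± 0.11, which was 0.60 ± 0.13 above coding regions (permutation p = 0.0001). Promoters exceeded these 3′ intergenic probes by 0.67 ± 0.04 (permutation p = 0.0001). The 2109 probes classed as other, also outside the frames used, averaged 1.17 ± 0.05. That is about as high as promoters, a comparison that was not tested. Dim probes were left out unevenly, with 27.3% of promoter, 27.2% of 3′ intergenic and 1.96% of coding probes not used for that reason.

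Within reading frames the ratio was lowest in the middle. The first part of frames, divided into 3 equal parts, averaged 0.10 ± 0.05, the middle part -0.47 ± 0.03 and the last part -0.02 ± 0.01. The first part exceeded the last by 0.12 ± 0.05 (permutation p = 0.0004), and the middle lay below the last, with a difference of -0.45 ± 0.04 (permutation p = 0.0001). Over 3556 genes of at least 1000 bp, the profile peaked at 1.04 ± 0.05 between 200 and 100 bp upstream of the start codon. It crossed the array median between 200 and 400 bp into the frame and was lowest at -0.51 ± 0.03 between 800 and 900 bp. Past the stop codon it was at 0.51 ± 0.11 in the nearest 100 bp.

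**Figure D2:**
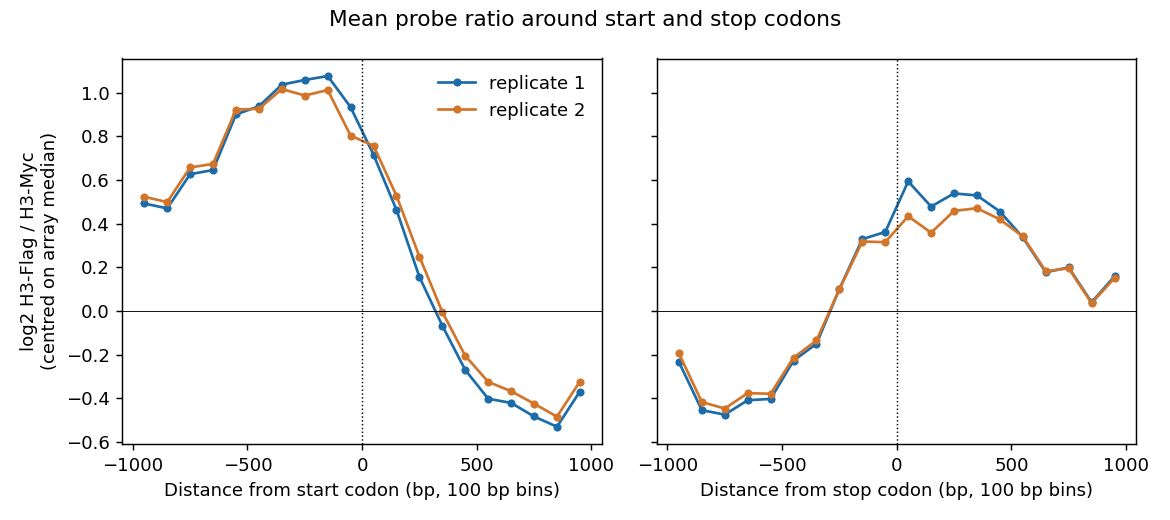
The mean log2 ratio of H3-Flag to H3-Myc is drawn in 100 bp bins around start codons (left) and stop codons (right) of 3556 genes of at least 1000 bp, with 1 line per replicate. Both replicates peak upstream of the start codon, near 1.04, and lie below 0 in the interior of the frame.

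In coding regions 9 of 22 gene lists passed camera. With 2 arrays, camera with an estimated correlation has too few degrees of freedom to reach the threshold. Its adjusted p, given beside each call, therefore cannot decide for or against a list. All 31 measured pheromone response genes were higher than the array median, and the list stood 2.29 ± 0.02 above other genes (camera adjusted p = 5.0e-11; adjusted p = 0.71 with an estimated correlation). FAR1, which arrests the cycle in response to pheromone, had 3.88 ± 0.09 and CIK1, a kinesin partner, 3.67 ± 0.10. KAR3, the kinesin, had 0.76 ± 0.07, and ERG24, a sterol reductase, 0.29 ± 0.23, a value that lost its call under 4 settings and was 0.12 without replicate 1 and 0.45 without replicate 2. All 6 measured histone genes were higher, by 2.39 ± 0.09 as a list (camera adjusted p = 0.0029; adjusted p = 0.71 with an estimated correlation). HHT2 had 3.95 ± 0.23 and HHT1 3.81 ± 0.42, although probes of both can read the tagged H3 constructs, and HHO1 (linker histone, 0.93 ± 0.13) and CSE4 (centromeric H3, 0.66 ± 0.09) were the lowest. Of 12 galactose genes 11 were higher, and the list stood 1.80 ± 0.07 above other genes (camera adjusted p = 0.0010; adjusted p = 0.71 with an estimated correlation). GAL2 and GAL1 led it, PCL10, a cyclin, had 0.26 ± 0.06, and the 1 lower member was FUR4. The call of PCL10 ended with normexp (0.163) and without the dim filter (0.164).

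Lists of energy metabolism were also higher in coding regions. Respiration genes stood 0.99 ± 0.07 above other genes, with 30 of 34 higher and 1 lower (camera adjusted p = 6.3e-07; adjusted p = 0.71 with an estimated correlation). Against random lists matched on frame length, a comparison added after the data were examined, the excess was 0.35 and lay inside their central 95%. CYC1, cytochrome c, had 3.34 ± 0.04 and QCR2, of complex III, 2.72 ± 0.06, while RIP1 had -0.24 ± 0.04, a call that loess ended, and SDH4 0.01 ± 0.28. Glycolysis genes stood 0.98 ± 0.24 above (camera adjusted p = 0.0016; adjusted p = 0.71 with an estimated correlation), with 16 of 18 higher. TEF1, the translation elongation factor placed in this list for its high expression, had 2.57 ± 0.08 and TDH3 2.52 ± 0.20, and PFK1 (-0.34 ± 0.02) and PDC5 (-0.87 ± 0.08) were the 2 lower members. Glucose-repressed genes stood 0.87 ± 0.28 above, with 20 of 27 higher and 6 lower (camera adjusted p = 0.023; adjusted p = 0.71 with an estimated correlation). YAT1 (carnitine acetyltransferase, 3.39 ± 0.30) and ADY2 (acetate transporter, 3.15 ± 0.13) led, and the maltose genes MAL11 (-1.12 ± 0.15) and MAL32 (-1.16 ± 0.14) were lowest. Cytosolic ribosomal protein genes stood 0.58 ± 0.10 above, with 90 of 122 higher and 8 lower (camera adjusted p = 2.2e-07; adjusted p = 0.71 with an estimated correlation), and 0.21 above lists matched on frame length, past their central 95% by less than the spread between arrays. RPL9B had 3.24 ± 0.03, RPS26B 3.03 ± 0.06, RPL23B -0.63 ± 0.24 and RPL37B -0.92 ± 0.06.

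Ribosome biogenesis went the other way in coding regions. It stood at -0.60 ± 0.05 against other genes, with 37 of 52 members lower and 6 higher (camera adjusted p = 0.0016; adjusted p = 0.71 with an estimated correlation). UTP22 had -1.46 ± 0.06 and NOP7 -1.32 ± 0.19, whereas KRR1 (2.03 ± 0.13) and RLP7 (1.29 ± 0.09) were the highest. Of the PAU, DAN and TIR genes, a family expressed without oxygen, 4 of 6 were lower and 0 higher, and the list differed by -1.13 ± 0.22 (camera adjusted p = 0.045; adjusted p = 0.71 with an estimated correlation). DAN4 had -1.57 ± 0.08 and TIR4 -1.36 ± 0.14, while TIR3 (-0.19 ± 0.25) and TIR2 (-0.23 ± 0.30) did not pass. Both passed as lower with normexp, and TIR2 also with loess and without the dim filter. Scaling the arrays or dropping the dim filter ended the call of this list.

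The remaining 13 lists did not pass camera in coding regions. The 3 measured silent mating genes were lower, a call that normexp ended for HMRA1 (-0.045), and the list differed by -1.40 ± 0.07 (camera adjusted p = 0.089), with HMLALPHA2 at -1.51 ± 0.15 and HMRA1 at -0.37 ± 0.13. HMRA1 DNA is also present at MAT in cells that answer alpha factor. Strain markers differed by 1.30 ± 0.01 (adjusted p = 0.13), from HHT2 down to CAN1, the arginine permease, at -1.25 ± 0.07 and LYS2 at -0.42 ± 0.07. Stress response differed by 0.51 ± 0.11 (adjusted p = 0.086), with HSP12 at 3.20 ± 0.47, SOD2 at 3.13 ± 0.00, HSP30 at -0.77 ± 0.17 and ALD3 at -1.35 ± 0.03. The phosphate regulon differed by 0.48 ± 0.00 (adjusted p = 0.19), with SPL2 at 2.86 ± 0.07 and VTC1 at 2.77 ± 0.06 against VTC2 at -1.08 ± 0.10. Amino acid biosynthesis differed by 0.33 ± 0.03 (adjusted p = 0.36), with HIS3 at 3.60 ± 0.18, LYS21 at 3.47 ± 0.11 and LEU1 at -1.23 ± 0.02. G2/M genes differed by -0.58 ± 0.06 (adjusted p = 0.076), G1/S genes by -0.28 ± 0.02 (0.22) and M/G1 genes by 0.11 ± 0.00 (0.70). In the first, CHS2 had -1.36 ± 0.02 and HOF1 -1.40 ± 0.11. Among the latter lists, PCL2, a G1 cyclin, had 3.02 ± 0.16 and TEC1, a transcription factor of filamentous growth, 3.49 ± 0.26, against SWI4 at -1.14 ± 0.01, MCM6 at -1.28 ± 0.02 and DSE4 at -1.32 ± 0.06. Proteasome genes differed by -0.38 ± 0.03 (adjusted p = 0.13), with PRE7 at 2.78 ± 0.01 and RPN9 at -1.24 ± 0.12. Histone chaperones and remodellers differed by -0.30 ± 0.05 (adjusted p = 0.23), with ASF1 at 2.58 ± 0.14, ARP6 at 2.43 ± 0.02, SWR1, the motor that deposits H2A.Z, at -1.22 ± 0.04 and HIR2 at -1.38 ± 0.13. COS genes (-0.28 ± 0.15), meiosis and sporulation (-0.18 ± 0.04) and mitochondrial ribosomal proteins (-0.07 ± 0.09) had adjusted p of 0.63 or more.

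In promoters 6 of 21 lists passed camera. The adjusted p with an estimated correlation has the same limit here. Strain markers stood 1.88 ± 0.00 above other promoters (camera adjusted p = 1.4e-05; adjusted p = 0.61 with an estimated correlation), or 1.25 above without the dim filter, and all 8 measured were higher than the array median, from HHT2 down to LEU2 at 1.64 ± 0.15. All 9 histone promoters were higher, and the list stood 1.52 ± 0.09 above (camera adjusted p = 0.00026; adjusted p = 0.61 with an estimated correlation), with HHO1 lowest at 0.61 ± 0.29 (0.41 without replicate 2). HHF2 and HHT2 share 1 promoter probe, which counts for both genes in both of these lists. The members are thus not all separate measurements, and the calls of the histone and strain marker lists are not independent. Glycolysis stood 0.90 ± 0.05 above with 13 of 13 higher (camera adjusted p = 0.011; adjusted p = 0.61 with an estimated correlation), led by PDC1 at 2.86 ± 0.16. Glucose-repressed promoters stood 0.79 ± 0.26 above with 20 of 22 higher (camera adjusted p = 0.0049; adjusted p = 0.61 with an estimated correlation), led by CIT2 at 3.82 ± 0.44 and the lactate permease JEN1 at 3.60 ± 0.38. Amino acid biosynthesis stood 0.54 ± 0.02 above with 26 of 29 higher (camera adjusted p = 0.043; adjusted p = 0.61 with an estimated correlation), led by LEU4 at 3.31 ± 0.17 and GCN4, the activator of these genes, at 3.27 ± 0.38. Normexp ended that call. The PAU, DAN and TIR promoters differed by -1.09 ± 0.08 (camera adjusted p = 0.0011; adjusted p = 0.61 with an estimated correlation), although 6 of 14 were above the array median and 6 below it, and their mean was near 0 (median 0.18).

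Of the 3 lists with the largest coding differences that passed camera, histones also passed in promoters, and galactose and pheromone response did not. Galactose promoters differed from others by 0.73 ± 0.03 (camera adjusted p = 0.060) and pheromone response promoters by 0.43 ± 0.02 (0.10), although all 11 and all 25 were above the array median. SST2, a regulator of pheromone signalling, had 3.07 ± 0.06 and MFA2, a pheromone gene, 2.77 ± 0.17 (1.35 without the dim filter), while TEC1 had 0.35 ± 0.10, a call that ended without the dim filter and with loess, which turned its sign (-0.0096). The other 13 lists differed by -0.50 to 0.58, with camera adjusted p of 0.0595 or more. Among their members, RPS3 (4.09 ± 0.07), RSM7 (3.57 ± 0.03), PRE7 (3.65 ± 0.15) and IME2, a meiotic kinase (3.38 ± 0.10), were high, and DIT1, a spore wall gene, was at -1.04 ± 0.24. Adjusted over the list alone, no count in a coding list changed except 1 more lower COS gene, and promoter counts changed by at most 1 gene per list.

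**Figure D3:**
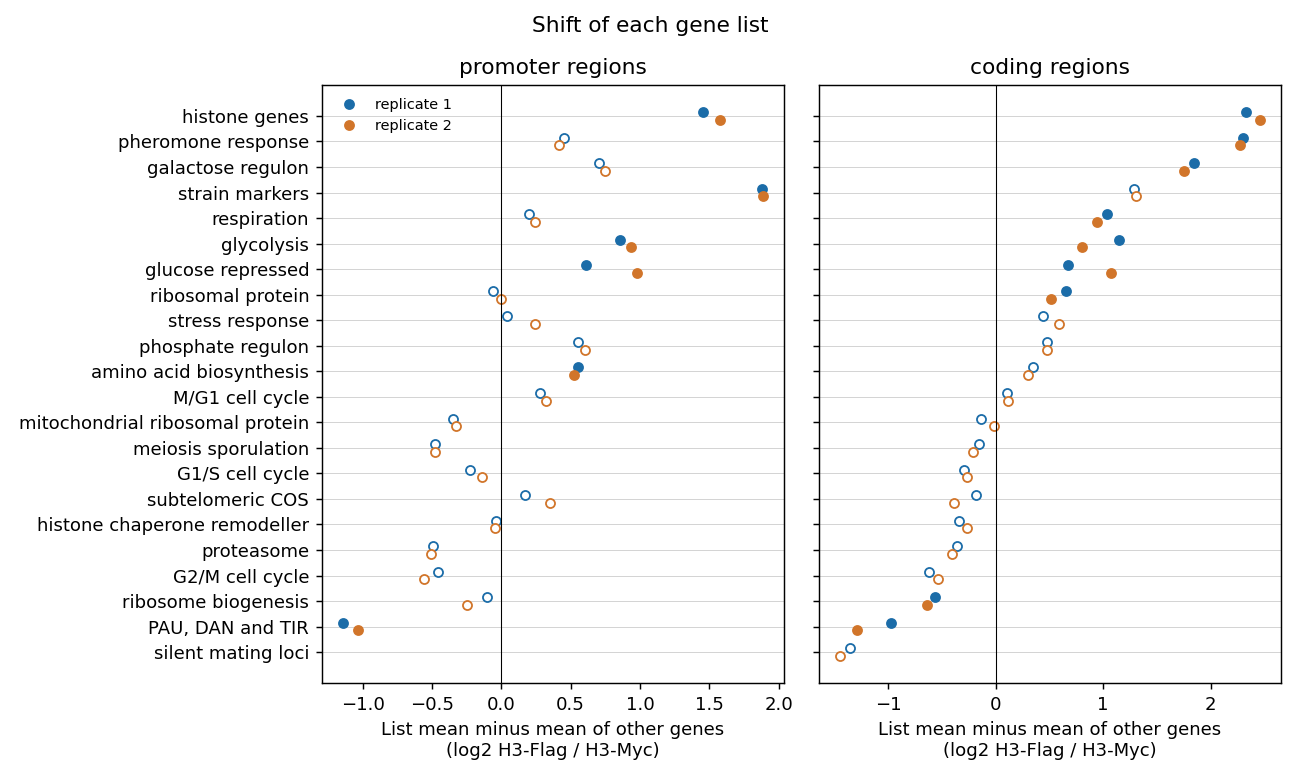
Each point is the mean log2 ratio of a gene list minus that of all other genes on 1 replicate, for promoters (left) and coding regions (right), with filled points where the camera adjusted p was under 0.05. In coding regions histone genes, pheromone response and galactose genes lie farthest right, at 2.39, 2.29 and 1.80, and on the left panel the latter 2 lie at 0.43 and 0.73.

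Chromosome ends were compared with the rest because H2A.Z is known to act next to silent chromatin. The 1238 probes within 20 kb of an end averaged 0.14 ± 0.03 and the others 0.18 ± 0.00, and the difference of -0.05 ± 0.03 did not pass (permutation p = 0.66). Coding probes, which had the lower ratio, were 541 of these 1238 but 25338 of the 33661 others. The pooled difference therefore mixes position with class and does not show that ends match the rest. Split by class, a comparison added after the data were examined, promoters near ends were lower than promoters elsewhere, 0.72 ± 0.02 over 198 probes against 1.16 ± 0.07, a difference of -0.45 ± 0.04 (permutation p = 0.00030), or -0.264 without the dim filter and -0.271 at 30 kb. Coding regions differed by -0.23 ± 0.04 (permutation p = 0.054), which passed with normexp and loess, and whether the classes differ was not tested. Of 32 ends, 18 were above the array median on both arrays and 12 below it. Of the features between genes, snoRNA genes were the ones that stood apart. For each of the 5 features, distance was taken from its listed left end, so probes beside the right end of a longer feature count as other. The 76 probes within 250 bp of the left end of an snoRNA gene exceeded other intergenic probes by 0.69 ± 0.09 (permutation p = 0.0021, adjusted over 5 features 0.010). The differences for tRNA genes (-0.05 ± 0.05, 220 probes), replication origins (0.01 ± 0.05, 39 probes), centromeres (-0.01 ± 0.03, 10 probes) and LTRs (-0.16 ± 0.00, 218 probes) did not pass, with adjusted permutation p of 0.47 or more.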

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

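The subtraction of mitochondrial signal was fixed before its result was seen, and the comparison with 3′ intergenic probes was chosen as a test of this pattern after its result was seen. Signal appeared on probes that the comparisons did not use: of 136 mitochondrial probes, 62 were well above background in the Flag channel on replicate 1 and 57 on replicate 2, although mitochondrial DNA carries no histones. In the Myc channel 28 and 31 were. The median mitochondrial probe had 8.05% and 10.7% of the nuclear median signal in the Flag channel and 3.26% and 2.48% in the Myc channel. Where both channels were well above background, the median log2 Flag over Myc was 0.77 and 0.45, above the nuclear median. No sample without a tag was analysed here, so no background level from such cells stands beside these values.

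The pattern weighed with it is the higher ratio of promoters than of coding regions. DNA carried into the precipitates without a histone may raise the ratio of regions that hold few nucleosomes. The median mitochondrial signal of each channel was subtracted from every probe used. The promoter minus coding difference was then 1.31 ± 0.13, above 0.63 (50% of its value) on both arrays. Most mitochondrial probes were not well above background, so the amount subtracted was small. Beforehand, 27.3% of promoter but 1.96% of coding probes had been left out as dim. That amount thus did not remove the difference among the probes used, and the test cannot decide on larger or uneven carry-over. An equal probe or dye effect on all DNA outside frames falls short of the whole, since promoters exceeded 3′ intergenic probes by 0.67 ± 0.04. Probes classed as other, however, averaged 1.17 ± 0.05, about as high as promoters at 1.15 ± 0.06. An effect that differs among kinds of DNA outside frames is therefore not excluded. The 0.60 by which 3′ intergenic probes exceeded coding probes stays open to a probe or dye effect, because no dye swap was analysed and probe sequences were not used here. No biological explanation was tested, since the design holds 1 group.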

How the results depend on the processing

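Counts of probes, promoters and coding regions past the threshold stayed within 1.5 times under each alternative run, and each location difference that passed, promoters near chromosome ends included, did so again with the same sign wherever an alternative had a test. The lists within genes, the matching on frame length and the silent cassettes were not run under other settings. The promoter minus coding difference was 1.101 with normexp, the lowest value over probes, and 0.89 as the mean of paired differences per gene, a mean in which long frames count no more than short ones. The correlation between arrays was 0.96 with normexp, 0.95 with loess and 0.96 without the dim filter. No paired analysis was possible because there is 1 group. Leaving out either replicate leaves 1 array and no test. The value table and the removal of saturated spots moved nothing and so say nothing on stability. A GC trend, probe uniqueness and leaving out dubious genes were not run, since probe sequences and a dubious class were not used here. With an estimated correlation, which 2 arrays leave with too few degrees of freedom to reach the threshold, none of the 15 list calls held. In promoters these were histones 1.52, glycolysis 0.90, glucose-repressed 0.79, amino acid biosynthesis 0.54, strain markers 1.88 and PAU, DAN and TIR -1.09. In coding regions they were galactose 1.80, pheromone response 2.29, histones 2.39, ribosomal proteins 0.58, respiration 0.99, glycolysis 0.98, glucose-repressed 0.87, ribosome biogenesis -0.60 and PAU, DAN and TIR -1.13. With fry on values centred on the mean of all genes, the promoter calls of histones (1.51), glycolysis (0.90), glucose-repressed (0.79), amino acid biosynthesis (0.53) and PAU, DAN and TIR (-1.09) ended. So did the coding calls of galactose (1.80), histones (2.39), ribosomal proteins (0.57), respiration (0.98), glycolysis (0.97), glucose-repressed (0.87), ribosome biogenesis (-0.59) and PAU, DAN and TIR (-1.13). Fry added calls for the promoters of pheromone response (0.43), proteasome (-0.50) and meiosis (-0.47), and for the coding regions of the phosphate regulon (0.48) and strain markers (1.30). Fry also has 1 residual degree of freedom here. Its p thus depends strongly on how closely the 2 arrays agree on a list mean, so calls gained or lost with it say little. Without the dim filter, the strain marker promoters stood at 1.25 and the difference of promoters near chromosome ends at -0.264, which was -0.271 at 30 kb. These were the list and location differences past the threshold that moved by over 1.5 times. The coding difference near chromosome ends passed with normexp (-0.218) and loess (-0.229). Without the dim filter, the promoters of galactose (0.82), pheromone response (0.32), mitochondrial ribosomal proteins (-0.35), proteasome (-0.48) and meiosis (-0.50) passed, and the coding call of PAU, DAN and TIR (-1.14) ended, as it did with scaling (-1.13). With normexp, the promoter call of amino acid biosynthesis (0.38) ended. Beyond the limits given for fry and the estimated correlation, the cause of these changes was not tested. Signs turned for 4 named promoters: TEC1 with loess (-0.0096), RPL40A (0.13) and SWI5 (0.14) with normexp, and ATP7 without the dim filter (0.46). Of the 10 highest and 10 lowest promoters and coding regions, values moved by over 1.5 times for the promoters of PAU20 (-1.03), DCG1 (-0.93), CFF1 (-0.85) and ADY3 (-0.67) with normexp, and for the coding regions of YCH1 (2.83) without the dim filter and of JIP3 (2.51) and PHO12 (-3.20) with loess. Of the other genes given, so did the promoters of MFA2 (1.35) and GCN4 (1.95) without the dim filter, and the coding regions of RIP1 (-0.38) and RPL37B (-0.48) with normexp and of HHO1 (0.59), HMLALPHA2 (-2.27), PFK1 (-0.63), HSP12 (2.10), VTC1 (1.68) and ASF1 (1.48) with loess. The promoter calls of RPL40A and SWI5 ended with normexp, and that of RPL40A also without the dim filter. Other calls that ended are given beside PCL10, FUR4, ERG24, RIP1, HMRA1 and TEC1. Some genes named by rule but given no value here also lost calls, among them the promoters of RPS29B and RPN8 with normexp. Signal over background limits probes outside frames, with 27.3% of promoter and 27.2% of 3′ intergenic probes dim.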

Other observations

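The comparisons of lists within genes, the tests by frame length of ribosomal proteins and respiration, the sets of genes as high as the markers and the values around the silent cassettes were chosen after the data were examined. In most genes the promoter had the higher ratio, and pheromone response genes reversed this. Over 23 of them the coding region exceeded the promoter by 1.07 ± 0.10, against -0.90 in other genes (permutation of genes, adjusted p = 0.0010 over 21 lists), with the coding region higher on both arrays in 19. Galactose genes, at -0.04 ± 0.02, also passed (adjusted permutation p = 0.026). Against random lists matched on frame length, pheromone response (adjusted permutation p = 0.0021) and galactose genes (0.010) passed as well. Cytosolic ribosomal proteins (-0.25 ± 0.05), respiration genes (-0.26 ± 0.02) and ribosome biogenesis (-1.35 ± 0.15) passed without matching (adjusted permutation p of 0.0010, 0.017 and 0.026) and did not with it (0.066, 0.61 and 0.071). The genes that follow were chosen after their values were seen. The 5 largest values of coding minus promoter among genes with a name were those of MIN4 (3.72), TEC1 (3.14), SPP2 (3.06), ICS3 (3.00) and FAR1 (2.94). The 5 lowest were those of MPT5, an RNA-binding repressor, with a promoter at 4.02 and a coding region at -0.71, SYG1 (3.36 and -0.90), KAP104, an import receptor (3.57 and -0.64), IME2 (3.38 and -0.81) and HAP1, a heme-responsive activator (4.16 and 0.00). The KAP104 promoter value rests on 1 probe (273896 to 273955) that also flanks the 3′ end of the GAL7 frame, so it cannot be assigned to KAP104 alone.

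The silent cassettes were lower than the DNA within 3 kb of them. The 2 probes in HML averaged -1.62 ± 0.01, against 0.49 ± 0.12 for 12 probes within 3 kb and -0.06 ± 0.02 for 20 probes 3 to 10 kb away. The 3 probes in HMR averaged -1.16 ± 0.19, against -0.07 ± 0.16 for 18 probes within 3 kb and -0.51 ± 0.18 for 44 probes 3 to 10 kb away. The last stretch holds EMA35, whose frame, at -1.72, was lower than the HMR mean. The DNA that the 3 HMR probes read, between HMRA1 and HMRA2 and in HMRA1, can also be present at MAT. The HMR mean is thus not that of the silent copy alone, and these differences were not tested. Of 4409 genes with at least 3 coding probes, BAR1 was the 1 gene with all, or all but 1, of its probes dim in both channels on both arrays. The labels name the HTZ1 deletion and no change at BAR1.

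A hypothesis for the high coding ratios of some lists is that short frames share precipitated fragments with the DNA around them and so take on its ratio. Across 5588 genes the coding ratio fell with frame length (Spearman rho = -0.50 across genes, which are not independent), from 0.91 ± 0.04 over the 1397 shortest frames to -0.46 ± 0.03 over the 1397 longest. Against random lists matched on frame length, respiration genes exceeded the mean by 0.35 and lay inside the central 95%, so frame length may account for that shift. Cytosolic ribosomal proteins exceeded it by 0.21, above the central 95% by less than the spread between arrays, which leaves the list open. The lengths matched include introns, and matching on coding length alone was not run. Pheromone response (2.33) and galactose genes (1.91) lay far above matched lists, which argues against frame length there. Histones (1.62), strain markers (1.13), glycolysis (1.06), glucose-repressed genes (1.05), stress response (0.59), M/G1 genes (0.46) and amino acid biosynthesis (0.46) were also above the central 95% of theirs. Below it were the silent mating genes (-1.93), the PAU, DAN and TIR genes (-1.12), mitochondrial ribosomal proteins (-0.57), proteasome (-0.46) and ribosome biogenesis (-0.44). The other 6 lists lay inside.

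URA3 (2.66 ± 0.16), HIS3 (3.60 ± 0.18) and TRP1 (2.51 ± 0.09) had high coding ratios, while LEU2 (0.21 ± 0.03), LYS2 (-0.42 ± 0.07) and ADE2 (-0.37 ± 0.08) did not. These genes were picked after their values were seen. The 3 genes exceeded their neighbouring coding regions by 2.14 on average, which argues against neighbourhoods as high as the genes. A smaller share of the neighbourhood in these values is not excluded. The excess is not particular to these genes, since 263 other genes as high exceeded their neighbours by 2.12 on average, and LEU2 did by 1.15. Frame length stays open, since 6.81% of genes of like length were at or above TRP1, against 4.29% for URA3 and 1.79% for HIS3. Extra copies on plasmids or marker cassettes of the strain, which each probe reads together with the chromosomal gene, may also raise these values and were not tested.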
